A study of Macaca fascicularis with 15 samples.

How the data were processed

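Each of the 11 deposited tables gives, per the file headers, 1 normalized signal value per gene for 1 library, already normalized by the authors in a way that no header or label states. GSNAP, a read aligner, and HTSeq, a read counting tool, are named in the submitters' notes without version. The genome build and the annotation behind the tables are not given in the sources used here, so no coordinates are printed and genes are named as in the tables. Of 12976 unique names, 9490 match symbols of a current annotation of this species. Samples were grouped by the tissue in their labels, where the animals are wild type, the tissue was kept in an RNA-preserving solution, and each sample comes from 1 eye. The labels state biological replicates for eye and retina, and give no animal, date or batch. For whole eye and whole retina, 2 records exist per numbered eye or retina, and 1 of each has a table.

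Each table has 13083 entries. Entries marked "ND" (27 in every library) were dropped, as were 61 exact duplicates of another entry. The 38 entries left under a repeated name were kept as separate entries and are not named singly. This left 12995 genes. Low values kept at full precision move in steps whose size depends on gene and library, as in values scaled by gene length and depth. Of 164 such genes, 44 (26.8%) were whole multiples of their step in every library, against 0 at 20 random sets of steps. The steps give the depth of the libraries relative to each other, known only up to a small whole factor. Some gene names share their start with another name, and in some libraries values of such genes appear exchanged: 2426 of the 11933 tested genes have such a name, and each is marked where it is named.

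The planned tests assumed read counts. As the tables hold normalized values, limma 3.58.1 (R 4.3.3) on log2(value + 1) took their place. Its linear model held 11 libraries in 4 groups, with a trend of variance with level. All groups share 1 variance per gene, set mostly by the regional libraries in every comparison. Genes with a mean of at least 1 in at least 1 group were tested, 11933 in all. Differences are the fitted difference of mean log2 values, tests are two-sided, and p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. The comparisons, fixed in advance, were central with peripheral retina, whole retina with whole eye, and central and peripheral retina each with whole retina. The last 2 share the whole retina libraries.

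The 28 gene lists were written before the data were examined: rod, cone and shared photoreceptor, bipolar, horizontal, amacrine and ganglion cells, Müller glia, astrocytes, microglia and other immune cells, vascular cells, pigment epithelium, melanin synthesis, lens, corneal and conjunctival epithelium, fibrous stroma and matrix, smooth muscle, skeletal muscle, blood, retinoid cycle, retinoic acid metabolism and receptors, carotenoid handling, photoreceptor ribbon synapse, glycolysis, nuclear-encoded oxidative phosphorylation, complement and macular degeneration risk, immediate early response, and heat shock. Each was tested with limma's camera at its preset correlation of 0.01 and with an estimated correlation; 27 lists had the 3 tested members needed, and horizontal cells had 1. Counts adjusted over the list alone repeat the Benjamini and Hochberg step over the members of that list.

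Named genes follow a rule fixed before the data were examined: the 8 largest differences per direction in central against peripheral retina and in whole retina against whole eye, and the 4 largest in the other comparisons. They had to pass the threshold, show no overlap of the groups' libraries and have a mean of at least 10 in the higher group; unnamed loci and repeated names were left out. The minimum of 10 was written for CPM and was applied to the deposited values. The rule adds up to 4 members per list by smallest p, and a fixed set of known marker genes. Of that set, OPN1MW, POU4F1, RBPMS, GFAP and CRYAA were not analysed here. Some genes that met the rule are left out of the text. After values were seen, genes were added where a list direction counts 5 members or fewer, and list members that did not pass were left out of the alternatives and of the check of single libraries. The count of calls per list that stayed with each library left out was added after the values were seen.

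The analysis was tried on simulated normalized tables with 200 changed genes each. In the order of comparisons above, it recovered 79.4%, 67.6%, 68.9% and 58.3% of 2-fold changes and 46.4%, 10.1%, 28.6% and 24.2% of 1.5-fold changes. Of the calls, 1.3%, 5%, 5% and 0.8% were false. These rates may not hold for the data, where more genes were called. Tables and plots were made with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.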

Results

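RNA sequencing compared the whole eye of the cynomolgus monkey with the retina and its regions. Tables were analysed for 11 of the 15 samples: 2 whole eyes, 2 whole retinas, 4 samples of central retina and 3 of peripheral retina. The other 4 records, 2 of whole eye and 2 of whole retina, were not analysed here. The central retina holds the macula, the area of sharpest vision, and the headers of the central tables use that name. Values have no stated unit, and absolute sequencing depth is unknown. Depth relative to the deepest library was lowest in central retina replicate 1 (31.5%) and lay between 58.1% and 96.5% in the other 9. Of 12995 genes, between 171 (whole eye replicate 1) and 501 (central retina replicate 1) were listed at 0 in a library. Whether the regional samples came from separate animals is not stated, so the p-values measure only the spread between these samples, which may be technical.

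Across the 11933 tested genes, which are not independent replicates, log2 values of central libraries correlated with each other at 0.968 to 0.986 and those of peripheral libraries at 0.973 to 0.98. The 2 whole eyes correlated at 0.969 and the 2 whole retinas at 0.953. Central with peripheral libraries gave 0.926 to 0.965. Whole retina correlated at 0.914 to 0.955 with whole eye, at 0.803 to 0.834 with central retina and at 0.838 to 0.875 with peripheral retina.

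Genes of retinal ganglion cells, the neurons that carry visual signals to the brain, were higher in central than in peripheral retina. All 10 tested members of that list were higher in central retina, both over all genes and, with 10, adjusted over the list alone, at a median log2 difference of 1.87, the largest of the 28 lists; 2 of the 10 have shared name starts. NEFL, the light chain of axonal neurofilaments, averaged 353 ± 81.6 (SD, n = 4) in central and 70.3 ± 23.4 (SD, n = 3) in peripheral retina, 5.02 times as much. SNCG, gamma-synuclein, averaged 1731 ± 574 against 339 ± 109. The transcription factor gene POU4F2 averaged 16.2 ± 2.64 against 3.65 ± 1.13. SLC17A6, which encodes a vesicular glutamate transporter, averaged 49.1 ± 9.56 against 12.9 ± 2.89. Each central library lay above each peripheral library for these 4 genes, and limma's adjusted p was 0.000133 for NEFL, 0.000324 for SNCG and 9.18e-05 for both POU4F2 and SLC17A6. For the list, camera gave adjusted p = 1.07e-10 at its preset correlation, a call lost at adjusted p = 0.212 with an estimated correlation. With each library left out in turn, 9 of the 10 calls stayed in every limma fit.

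**Figure D1:**
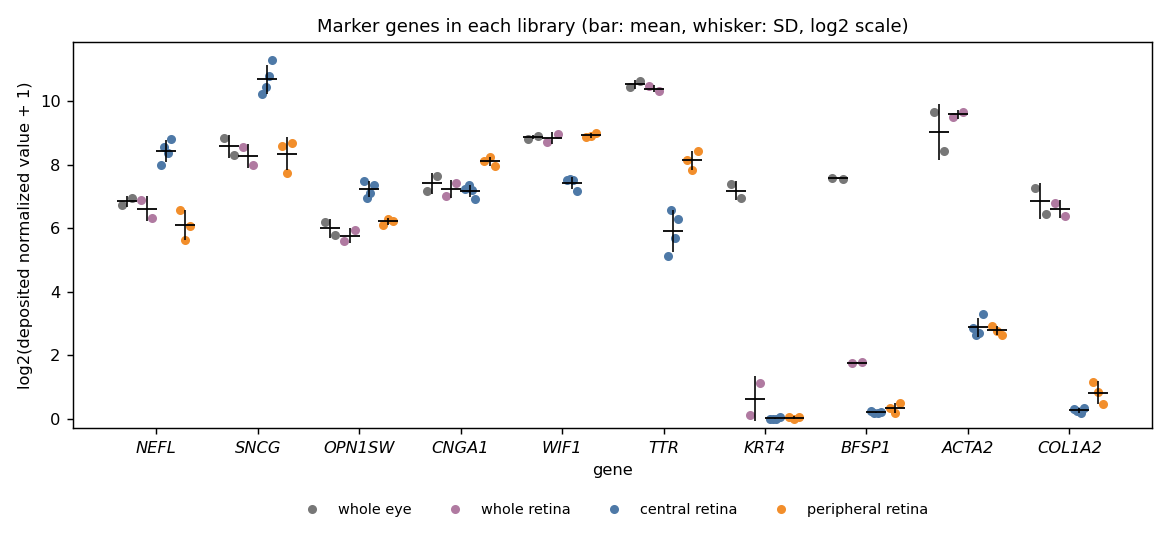
Log2 of the deposited value plus 1 for 10 genes in 11 libraries. Grey, whole eye (n = 2); purple, whole retina (n = 2); blue, central retina (n = 4); orange, peripheral retina (n = 3). Points are libraries, bars are group means of log2 values and whiskers are SD.

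Part of the rod genes were lower and part of the cone genes higher in central than in peripheral retina. Of 13 rod genes, 6 were lower and 0 higher by limma, where an unadjusted p under 0.05 also gave 0 higher and 8 lower; 7 were lower adjusted over the list alone, and the median was −0.49. Of 15 cone genes, 4 were higher (OPN1SW, RXRG, SLC24A2 and OPN1LW) and 4 adjusted over the list alone, with a median of 0.22. Of 18 genes used by both rods and cones, 9 were lower and 11 adjusted over the list alone, with a median of −0.46. CNGA1, a subunit of the rod channel gated by cyclic GMP, averaged 145 ± 18.1 in central and 278 ± 27.9 in peripheral retina (limma adjusted p = 0.00187). OPN1SW, the opsin of short-wavelength cones, averaged 151 ± 25.6 against 73.6 ± 5.13 (limma adjusted p = 0.00115). RXRG, a retinoid receptor gene, averaged 68.0 ± 14.0 against 28.3 ± 5.62 (limma adjusted p = 0.000573). IMPG1, a gene of the matrix between photoreceptors, averaged 236 ± 32.8 against 355 ± 9.43 (limma adjusted p = 0.00605). The call on OPN1LW, the long-wavelength opsin gene at 378 ± 52.9 against 249 ± 31.3, had a limma adjusted p of 0.0116 and was lost without peripheral retina replicate 2, at 0.0636, the highest of its alternatives. Over all fits with 1 library left out, 1 of the 6 rod calls, 3 of the 4 cone calls and 4 of the 9 shared calls stayed. The rod calls on GNGT1, NR2E3 and SAG were lost without any 1 of 6, 4 and 2 libraries, at a limma adjusted p of up to 0.112, 0.113 (both without peripheral retina replicate 2) and 0.0714 (without peripheral retina replicate 3).

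By camera the rod list gave adjusted p = 0.000171, and adjusted p = 0.33 with an estimated correlation. The cone list gave a camera adjusted p = 0.0413, and adjusted p = 0.433 with an estimated correlation. That call was also lost without central retina replicate 1 or 2 or peripheral retina replicate 2 or 3 (limma camera adjusted p = 0.0579, 0.119, 0.069 and 0.0811). The shared list gave a camera adjusted p = 4.8e-05, and adjusted p = 0.33 with an estimated correlation. Several well-known photoreceptor genes did not pass. GNAT1, the rod transducin subunit, averaged 2838 ± 671 against 3969 ± 957 (limma adjusted p = 0.153), and its cone counterpart GNAT2 averaged 118 ± 17.6 against 103 ± 23.1 (limma adjusted p = 0.374). Cone arrestin (ARR3), a gene with a shared name start, averaged 681 ± 79.7 against 596 ± 51.7 (limma adjusted p = 0.4).

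Genes of Müller glia, the supporting cells that span the retina, were lower in central retina: 8 of 11 over all genes and 9 adjusted over the list alone, at a median of −0.77. WIF1, an inhibitor of Wnt signals, averaged 174 ± 21.2 against 489 ± 24.1 (limma adjusted p = 5.43e-05). RLBP1, which encodes a retinal-binding protein, averaged 199.8 ± 15.9 against 444 ± 81.7 (limma adjusted p = 0.000284). The camera adjusted p of the list was 3.17e-07, and adjusted p = 0.212 with an estimated correlation. Of 3 astrocyte genes, 2 were lower (ALDH1L1 and GJA1, the latter with a shared name start) and 2 adjusted over the list alone. ALDH1L1 averaged 1.17 ± 0.264 against 2.82 ± 0.839 (limma adjusted p = 0.00875). For the astrocyte list, with a median of −0.80, camera gave adjusted p = 0.0161, and adjusted p = 0.322 with an estimated correlation. Of the 8 Müller glia calls, 6 stayed whichever library was left out.

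Genes of the pigment epithelium, the pigmented layer behind the photoreceptors, were lower in central retina as well. Of 7 such genes, 6 were lower and 6 adjusted over the list alone, with a median of −1.43. TTR, which encodes transthyretin, a partner of the retinol-binding protein, averaged 64.3 ± 27.3 against 287 ± 58.9 (limma adjusted p = 0.000445). RGR, an opsin gene of the pigment epithelium and Müller glia, averaged 15.9 ± 5.00 against 70.5 ± 13.9 (limma adjusted p = 0.000111). The remaining member, RPE65, averaged 5.65 ± 0.915 against 6.89 ± 0.658 (limma adjusted p = 0.185), and its name shares its start with that of RPE. Values under RPE were 8.35 to 33.48 in central and 47.58 to 100.45 in peripheral retina. In the whole retinas and whole eyes RPE was 15.4 to 22.24 and RPE65 223.79 to 285.76. Part of the RPE65 signal of the regions may therefore be listed under RPE, which was not tested. The camera adjusted p of the list was 5.86e-06, and adjusted p = 0.322 with an estimated correlation. Of 7 melanin synthesis genes, 5 were lower (MLANA, SLC45A2, and TYR, TYRP1 and DCT with shared name starts) and 6 adjusted over the list alone. DCT was named after its values were seen. SLC45A2, a gene of pigment granules, averaged 0.33 ± 0.0808 against 2.87 ± 0.13 (limma adjusted p = 5.2e-05). The melanin list had a median of −1.44 and a camera adjusted p = 1.89e-05, and adjusted p = 0.153 with an estimated correlation.

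Genes of the retinoid cycle, which restores the light-sensitive pigment, were lower in central retina in 9 of 11 cases, and 9 adjusted over the list alone. The median was −1.13, and this list alone of 11 past camera's preset test (adjusted p = 3.17e-07) held with an estimated correlation, at adjusted p = 0.0309. The list shares 5 members with the pigment epithelium list. RDH10, a retinol dehydrogenase gene, averaged 20.2 ± 5.39 against 82.0 ± 10.5 (limma adjusted p = 0.000145). RDH5, of the same enzyme group, averaged 19.7 ± 5.91 against 70.5 ± 22.7 (limma adjusted p = 0.000415). Of the 9 calls, 7 stayed whichever library was left out.

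Glycolysis genes were higher in central retina, in 9 of 15 entries (2 of them under a single repeated name) and 10 adjusted over the list alone, with a median of 0.63. Of the 9 calls, 5 stayed whichever library was left out. ALDOC, a brain-type aldolase gene, averaged 1393 ± 309 against 656 ± 80.6 (limma adjusted p = 0.0012). PGK1 averaged 274 ± 48.7 against 159 ± 10.7 (limma adjusted p = 0.00351). For the list, camera gave adjusted p = 2.93e-05, and adjusted p = 0.33 with an estimated correlation. Of 14 genes of fibrous stroma and matrix, 5 were lower (FMOD, LUM, OGN, and FBLN1 and SPARC with shared name starts) and 1 higher (MMP2, shared name start). Adjusted over the list alone, 6 were lower and 1 higher. LUM and MMP2 were named after their values were seen. FMOD, fibromodulin, averaged 0.89 ± 0.508 against 4.39 ± 0.454 (limma adjusted p = 0.000461). The stroma list had a median of −0.42 and a camera adjusted p = 0.0102, and adjusted p = 0.33 with an estimated correlation. The limma adjusted p of MMP2, LUM and OGN passed 0.05 without peripheral retina replicate 1, at 0.147, 0.126 and 0.0914, and without peripheral retina replicate 2 or central retina replicate 4 as well.

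The other 17 lists did not pass camera between the regions or, with 1 member, were not tested. Of these, the complement list passed without central retina replicate 3 or 4 or peripheral retina replicate 1 or 2 (limma camera adjusted p = 0.0493, 0.0317, 0.0355 and 0.0237). Of 13 genes of retinoic acid metabolism and its receptors, 6 were lower and 1 higher (RXRG), and 6 and 1 adjusted over the list alone, with a median of −0.28 and a limma camera adjusted p = 0.106. Of the 6 lower calls, 3 stayed whichever library was left out. ALDH1A1, which makes retinoic acid, averaged 1.56 ± 0.309 against 6.92 ± 1.30 (limma adjusted p = 9.83e-05). RARB, a retinoic acid receptor gene, averaged 4.76 ± 1.01 against 9.61 ± 0.954 (limma adjusted p = 0.00383). CYP26A1, which breaks retinoic acid down, averaged 9.28 ± 2.02 against 5.60 ± 4.67 (limma adjusted p = 0.128), and passed without peripheral retina replicate 3, at 0.00635. Of 6 carotenoid handling genes, 2 were lower (BCO2 and APOE) and 2 adjusted over the list alone. That list's median was 0.03 and its mean −0.26, and its median was −0.06 after quantile normalization. BCO2, a carotenoid-cleaving enzyme gene, averaged 8.70 ± 1.30 against 19.4 ± 4.25 (limma adjusted p = 0.0086). Of 6 genes of complement and macular degeneration risk, 3 were lower (APOE, CFB and TIMP3) and 1 higher (VEGFA), and 3 and 1 adjusted over the list alone (limma camera adjusted p = 0.0523). TIMP3, a metalloproteinase inhibitor gene, averaged 53.5 ± 5.04 against 163 ± 22.5 (limma adjusted p = 5.43e-05). The VEGFA call was lost without any 1 of 6 libraries, at a limma adjusted p of up to 0.141 (without peripheral retina replicate 1 or 2).

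Among heat shock genes 1 of 9 was lower (CRYAB) and 1 adjusted over the list alone. CRYAB, a small heat shock protein gene, averaged 28.4 ± 5.81 against 95.3 ± 11.5 (limma adjusted p = 0.000111). Among lens genes 1 of 16 was higher (CRYBA2) and 1 adjusted over the list alone, while the list's median was −0.01 and its mean 0.08. CRYBA2 averaged 10.8 ± 4.09 against 1.78 ± 0.859 (limma adjusted p = 0.000443). Of 10 bipolar cell genes, 1 was higher (PCP2, shared name start) and 1 adjusted over the list alone. Of 12 ribbon synapse genes, 1 was higher (SNAP25) and 1 lower (UNC13B), and 2 and 2 adjusted over the list alone. SNAP25, a gene of vesicle fusion, averaged 807 ± 90.5 against 503 ± 17.7 (limma adjusted p = 0.00256).

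In the next lists of central against peripheral retina, each limma call was lost without at least 1 library. Of 24 oxidative phosphorylation genes, 3 were higher (among them CYC1 and, with a shared name start, UQCRC1) by limma over all genes and 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05. Of 8 immediate early genes, 1 was higher (ATF3) over all genes and 0 by limma adjusted over the list alone, with 4 at an unadjusted p under 0.05. The oxidative phosphorylation list passed limma's camera without central retina replicate 1 or 3 (adjusted p = 0.0156 and 0.0493), and the immediate early list without central retina replicate 2 or 3 or peripheral retina replicate 3 (0.0293, 0.0493 and 0.0171). The calls on UQCRC1, CYC1 and ATF3 were lost without peripheral retina replicate 2, at limma adjusted p of 0.122, 0.18 and 0.15. Of 10 amacrine cell genes, 1 was lower (SLC17A8) and 1 adjusted over the list alone. Of 8 vascular genes, 1 was lower (KDR) and 1 adjusted over the list alone. The list's median was 0 and its mean −0.1. The calls on SLC17A8, KDR and UNC13B were lost without peripheral retina replicate 1, at limma adjusted p of 0.0896, 0.135 and 0.181. By limma 0 of 9 immune cell genes, 0 of 7 genes of corneal and conjunctival epithelium, 0 of 6 smooth muscle genes, 0 of 6 skeletal muscle genes, 0 of 3 blood genes and the 1 horizontal cell gene passed, and 0 in each adjusted over the list alone. At an unadjusted p under 0.05 limma gave 1 lower gene each in the immune and corneal lists and 0 in the other 4. The blood list had a median of −0.03 and a mean of 0.05.

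**Figure D2:**
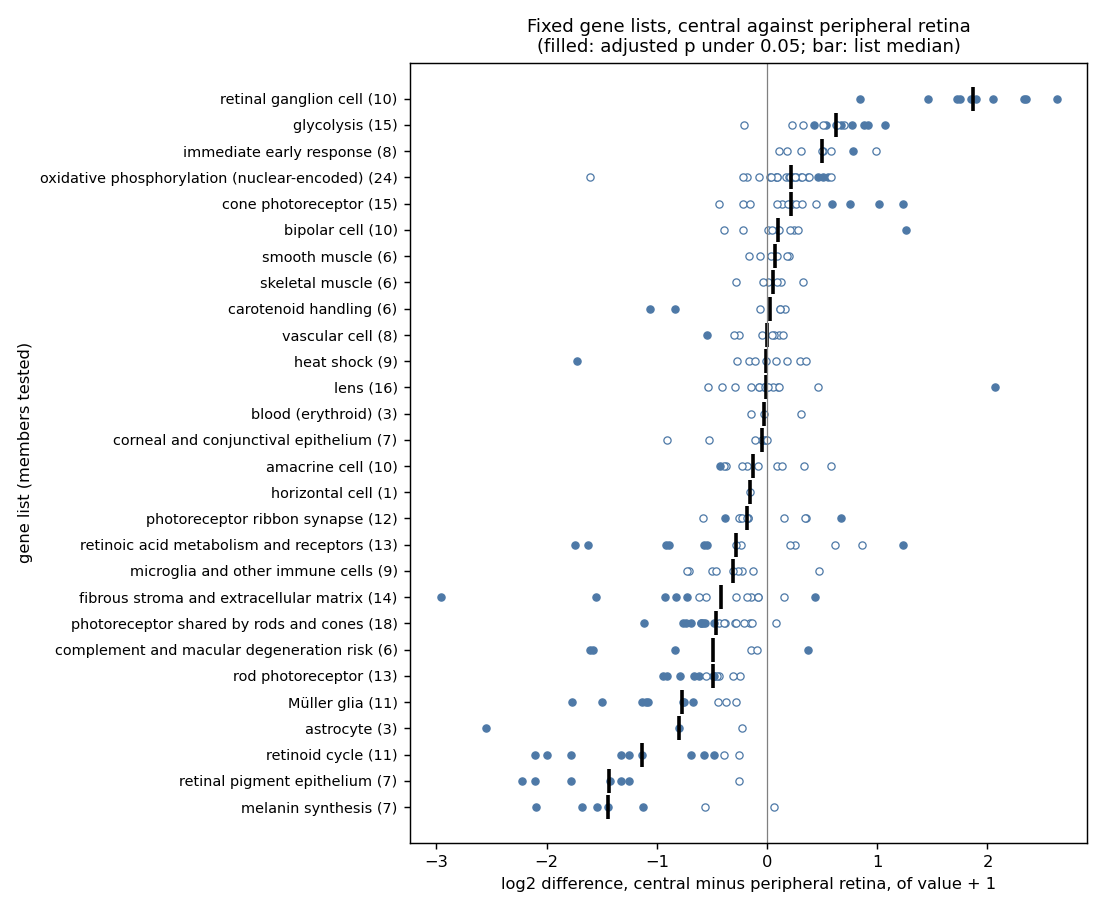
Log2 difference between central and peripheral retina for the members of 28 gene lists, with the number of tested members in parentheses. Filled points have a limma adjusted p under 0.05, open points do not, and vertical bars mark list medians.

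The largest differences that met the naming rule included transcription factor, matrix and pigment cell genes outside the lists. NEFM, another neurofilament gene and already counted in the ganglion cell list, averaged 267 ± 82.9 against 42.4 ± 13.6 (limma adjusted p = 7.76e-05). IRX1, a homeobox gene, averaged 13.4 ± 2.29 against 1.81 ± 0.597 (limma adjusted p = 2.53e-05). The open reading frame C20orf46 averaged 61.9 ± 19.6 against 9.31 ± 2.08 (limma adjusted p = 5.2e-05). OPTC, the matrix protein opticin, averaged 0.15 ± 0.0622 in central and 38.9 ± 31.8 in peripheral retina (limma adjusted p = 0.000147). The collagen genes COL2A1 and COL9A1 averaged 1.05 ± 0.542 against 17.0 ± 5.93 and 1.64 ± 1.87 against 24.2 ± 4.35 (limma adjusted p = 5.2e-05 and 0.000147). GPNMB, a melanosome glycoprotein gene, averaged 0.873 ± 0.257 against 14.0 ± 1.29 (limma adjusted p = 2.05e-06). AZGP1 averaged 8.22 ± 8.51 against 50.3 ± 22.5 (limma adjusted p = 0.0103).

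The rule also named FAIM, HR, GPR146, FAIM3, SLC25A31 and KCNJ13, all with names that share their start with another gene. FAIM averaged 55.8 ± 8.92 in central and 0.0633 ± 0.0351 in peripheral retina, while FAIM3 averaged 0.05 ± 0.0245 and 29.0 ± 3.64, a mirror image. KCNJ13, a potassium channel gene of the pigment epithelium, averaged 1.38 ± 0.893 against 13.2 ± 0.834 (limma adjusted p = 5.2e-05). SLC25A31, at 0.318 ± 0.152 against 112 ± 96.8, lost its call without central retina replicate 4, peripheral retina replicate 1 or peripheral retina replicate 2 (limma adjusted p = 0.0529, 0.0865 and 0.0973).

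In total, 1493 genes were higher and 1045 lower in central retina (limma, adjusted p under 0.05), 21.3% of those tested. Of these, 322 and 194 differed at least 2-fold in the fitted log2 difference. The median over all genes was −0.014, and 501 calls fell on genes whose names share a start. Without peripheral retina replicate 2, 829 were higher and 499 lower; the lower count was 655 without central retina replicate 3, 610 without central retina replicate 4 and 618 without peripheral retina replicate 1. Of simulated changes at levels of at least 10, the test found 79.4% at 2-fold and 46.4% at 1.5-fold.

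The whole retina lacked most transcripts of the lens and of the corneal surface, compared with the whole eye. Of 16 lens genes, 14 were lower and 16 adjusted over the list alone, with a median of −3.46. Of the 14 calls, 13 stayed whichever library was left out. BFSP1, a filament gene of the lens, averaged 2.42 ± 0.0283 (SD, n = 2) in whole retina and 190 ± 1.27 (SD, n = 2) in whole eye (limma adjusted p = 2.64e-09). Its partner BFSP2 averaged 2.08 ± 0.594 against 102 ± 1.65 (limma adjusted p = 4.91e-08). The crystallin gene CRYBA4 averaged 14.6 ± 2.95 against 293 ± 31.2 (limma adjusted p = 5.4e-07). All 7 genes of corneal and conjunctival epithelium were lower, and 7 adjusted over the list alone, with a median of −4.69. KRT4, a keratin gene of moist surfaces, averaged 0.655 ± 0.785 against 146 ± 30.4 (limma adjusted p = 1.09e-07). KRT12, the keratin gene of the cornea, averaged 14.6 ± 19.3 against 556 ± 19.4 (limma adjusted p = 0.00301, and 0.0666 with a replicate block, the replicate number added to a fit of only these groups). By camera both lists held, the lens at adjusted p = 1.78e-44 and 0.00119 with an estimated correlation, the cornea at adjusted p = 1.27e-25 and 0.000298 with an estimated correlation.

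Most skeletal muscle and blood genes were also lower in whole retina than in whole eye. Of 6 skeletal muscle genes, 5 were lower (ACTA1, TNNC2, MYH2, and MB and MYH1 with shared name starts) and 6 adjusted over the list alone, with a median of −2.62. MYH2, named after its values were seen, lost its call without whole retina replicate 1 (limma adjusted p = 0.131). Skeletal actin (ACTA1) averaged 0.555 ± 0.0354 against 24.1 ± 22.1 (limma adjusted p = 0.00144). With the replicate block the calls on ACTA1, TNNC2, MYH1 and ALAS2 were lost (limma adjusted p = 0.0592, 0.0832, 0.0654 and 0.0609), and that on TNNC2 also in a fit of only these groups (0.0561). The skeletal muscle list gave a camera adjusted p = 3.1e-12, and adjusted p = 0.108 with an estimated correlation. Of 3 blood genes, 2 were lower (ALAS2 and HBB) and 3 adjusted over the list alone, with a median of −3. ALAS2, a heme synthesis gene of red cells, averaged 0.23 against 3.10 (limma adjusted p = 9.07e-06). The HBB call was lost without whole eye replicate 1, whole eye replicate 2 or whole retina replicate 1 (limma adjusted p = 0.0802, 0.25 and 0.276). The blood list gave a camera adjusted p = 2.6e-06, and adjusted p = 0.108 with an estimated correlation.

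Between whole retina and whole eye, by limma 0 of 13 rod, 0 of 15 cone, 0 of 18 shared photoreceptor, 0 of 10 ganglion cell and 0 of 11 Müller glia genes passed, and 0 in each adjusted over the list alone. At an unadjusted p under 0.05 limma gave 1 higher rod gene, 3 higher shared photoreceptor genes, 2 lower ganglion cell genes and 0 in the other lists. The shared photoreceptor list, with a median of 0.17, gave a camera adjusted p = 0.0315, and adjusted p = 0.69 with an estimated correlation. It did not pass without whole eye replicate 1 or whole retina replicate 2 (limma camera adjusted p = 0.422 and 0.234). The rod list passed without whole eye replicate 2 and the ganglion cell list, which was lower, without whole retina replicate 1 (limma camera adjusted p = 0.0373 and 0.00546). CRX, a photoreceptor transcription factor gene, averaged 128 ± 12.8 against 97.5 ± 18.2 (limma adjusted p = 0.485). RPE65, with a shared name start, averaged 246 ± 31.2 against 273 ± 17.6 (limma adjusted p = 0.78). COL1A1, a collagen gene of stroma, averaged 23.5 ± 7.38 against 51.4 ± 29.3 (limma adjusted p = 0.237), and passed without whole eye replicate 2, at 0.00543. TYRP1, a melanin gene with a shared name start, averaged 243 ± 13.9 against 374 ± 142 (limma adjusted p = 0.626).

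Between whole retina and whole eye, 4 more lists passed camera although 0 of their genes passed limma over all genes. The immune list (0 of 9, 0 adjusted over the list alone, 3 at an unadjusted limma p under 0.05) was higher in whole retina at a median of 0.58, with a camera adjusted p = 0.00265, and adjusted p = 0.524 with an estimated correlation. The vascular list (0 of 8, 3 adjusted over the list alone, 3 at an unadjusted limma p under 0.05) was higher at a median of 0.34, with a camera adjusted p = 0.0128, and adjusted p = 0.515 with an estimated correlation. The smooth muscle list (0 of 6, 2 adjusted over the list alone, 3 at an unadjusted limma p under 0.05) was higher at a median of 0.62, with a camera adjusted p = 0.00571, and adjusted p = 0.515 with an estimated correlation. The melanin list (0 of 7, 0 adjusted over the list alone, 1 at an unadjusted limma p under 0.05) was lower at a median of −0.54, with a camera adjusted p = 0.032, and adjusted p = 0.515 with an estimated correlation. Without genes whose names share a start, the melanin and smooth muscle lists no longer passed limma's camera (adjusted p = 0.372 and 0.106). Each of these 4 calls rested on single libraries. The immune call was lost without whole retina replicate 1 (limma camera adjusted p = 0.442), where the list's median was 0.141, and the vascular call without whole retina replicate 2 (0.0526). The smooth muscle call was lost without whole eye replicate 2 or whole retina replicate 2 (limma camera adjusted p = 0.513 and 0.217). The melanin call was lost without whole eye replicate 1, whole retina replicate 1 or whole retina replicate 2 (limma camera adjusted p = 0.448, 0.201 and 0.0791).

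In the other lists of whole retina against whole eye few genes passed and camera gave no call with all libraries in the fit. In a fit of only these groups, limma's camera called the retinoid cycle and immediate early lists (adjusted p = 0.0465 and 0.0271). The stroma list, lower in whole retina, passed without whole eye replicate 2 and the oxidative phosphorylation list, also lower, without whole retina replicate 2 (limma camera adjusted p = 0.0275 and 0.00403). Of 13 retinoic acid genes, 1 was higher (ALDH1A2) and 1 lower (ALDH1A1), and 1 and 2 adjusted over the list alone. Both calls were lost without whole retina replicate 1 (limma adjusted p = 0.116 for ALDH1A2 and 0.185 for ALDH1A1). Of 10 amacrine cell genes, 1 was lower (TFAP2C) and 2 adjusted over the list alone. The TFAP2C call was lost in a fit of only these groups and with the replicate block (limma adjusted p = 0.173 and 0.303). Of 8 immediate early genes, 1 was higher (EGR1) and 1 adjusted over the list alone. By limma 0 genes passed in the bipolar, horizontal, astrocyte, pigment epithelium, stroma, retinoid cycle, carotenoid, ribbon synapse, glycolysis, oxidative phosphorylation, complement and heat shock lists, and 0 adjusted over each list alone. At an unadjusted p under 0.05 limma gave 3 lower stroma genes, 2 higher retinoid cycle genes, 1 higher ribbon synapse gene, 1 lower complement gene, 1 lower heat shock gene and 0 in the other 7. The astrocyte list had a median of 0.08 and a mean of −0.02.

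The largest higher genes in whole retina were few and mostly depended on single libraries. CXCL13, a chemokine gene with a shared name start, was 48.43 and 346.4 in the whole retinas and averaged 0.84 ± 0.566 in whole eye (limma adjusted p = 0.000116). CXCL12 and CXCL14 have names that start like that of CXCL13. In whole retina replicate 2, which gave the 346.4, they were 0.29 and 0.06. In whole retina replicate 1 and the whole eyes they were 31.75 to 67.23 and 77.54 to 180.86. The call may therefore rest on values of other genes under the name CXCL13. EGR1, an immediate early transcription factor gene, averaged 20.3 ± 0.594 against 6.97 ± 2.02 (limma adjusted p = 0.00492), and lost its call without whole eye replicate 1 and with the replicate block, at 0.0502 and 0.052. Of the 8 named higher genes, 7 lost their call without at least 1 library. In total 20 genes were higher and 251 lower in whole retina (limma, adjusted p under 0.05), 11 and 206 of them at least 2-fold, with 1265 at an unadjusted p under 0.05. With 2 libraries per group, the higher count was 493 without whole retina replicate 2 and 56 without whole eye replicate 1. Of simulated changes at levels of at least 10, the test found 67.6% at 2-fold and 10.1% at 1.5-fold.

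The whole retina held far more transcripts of stroma, smooth muscle, pigment cells and immune cells than the central retina. All 14 stroma genes were lower in central retina and 14 adjusted over the list alone, with a median of −3.85. Of the 14 calls, 12 stayed whichever library was left out. COL1A2, a collagen gene of fibrous tissue, averaged 0.208 ± 0.0608 in central and 97.6 ± 19.4 in whole retina (limma adjusted p = 9.93e-09). All 6 smooth muscle genes were lower and 6 adjusted over the list alone, with a median of −4.84. Smooth muscle actin (ACTA2) averaged 6.49 ± 1.68 against 771 ± 68.2 (limma adjusted p = 2.8e-08). All 7 pigment epithelium genes were lower and 7 adjusted over the list alone, with a median of −3.50. TTR averaged 64.3 ± 27.3 against 1356 ± 93.9 (limma adjusted p = 1.27e-06). All 7 melanin genes were lower and 7 adjusted over the list alone, with a median of −3.93. MLANA, a melanosome gene, averaged 0.09 ± 0.0606 against 144 ± 2.02 (limma adjusted p = 3.47e-10). The camera adjusted p was 7.93e-09 for stroma, 2.97e-05 for smooth muscle, 2.62e-05 for pigment epithelium and 7.47e-06 for melanin, and adjusted p = 0.0768, 0.166, 0.208 and 0.0768 with an estimated correlation.

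Most immune, vascular and lens genes were lower in central than in whole retina too. Of 9 immune genes, 8 were lower and 8 adjusted over the list alone, with a median of −3.32. CD74, a gene of antigen presentation, averaged 20.8 ± 3.39 against 729 ± 595 (limma adjusted p = 3.14e-06). Of 8 vascular genes, 6 were lower and 6 adjusted over the list alone, with a median of −1.67. CDH5, the cadherin gene of vessel lining, averaged 1.22 ± 0.0876 against 7.40 ± 0.955 (limma adjusted p = 2.91e-06). Of 16 lens genes, 11 were lower and 12 adjusted over the list alone, with a median of −1.52. CRYBB2, a crystallin gene, averaged 0.705 ± 0.288 against 329 ± 109 (limma adjusted p = 2.89e-08). By camera the adjusted p was 0.0007 for immune, 0.00379 for vascular and 5.36e-05 for lens genes, and adjusted p = 0.25, 0.222 and 0.166 with an estimated correlation. Of 7 corneal genes, 5 were lower (ALDH3A1, KRT12, KRT4, S100A8 and S100A9) and 5 adjusted over the list alone (limma camera adjusted p = 0.104, and 0.0315 without whole retina replicate 1). KRT4 was named after its values were seen. The KRT12 and KRT4 calls were lost without whole retina replicate 2 (limma adjusted p = 0.275 and 0.603) and that on S100A8 without whole retina replicate 1 (limma adjusted p = 0.17).

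Most ganglion cell, cone, bipolar and amacrine cell genes were higher in central than in whole retina. The medians of the cone, bipolar and amacrine lists were also positive in peripheral against whole retina (0.38, 0.39 and 0.50). All 10 ganglion cell genes were higher and 10 adjusted over the list alone, with a median of 1.8. NEFM averaged 267 ± 82.9 against 49.9 ± 8.08 (limma adjusted p = 3.58e-05). Of 15 cone genes, 9 were higher and 1 lower (CNGB3), and 10 and 1 adjusted over the list alone, with a median of 0.50. OPN1SW averaged 151 ± 25.6 against 54.1 ± 8.85 (limma adjusted p = 5.14e-05). Of 10 bipolar cell genes, 7 were higher and 0 lower by limma, with 1 lower at an unadjusted p under 0.05, and 7 and 1 adjusted over the list alone, with a median of 0.58. GRIK1, a glutamate receptor gene, averaged 35.5 ± 6.36 against 17.2 ± 2.96 (limma adjusted p = 0.00128). Of 10 amacrine cell genes, 6 were higher and 2 lower (SLC17A8 and SLC6A9), and 7 and 2 adjusted over the list alone, with a median of 0.50. SLC32A1, which encodes a transporter of inhibitory transmitters, averaged 32.1 ± 4.34 against 14.3 ± 0.191 (limma adjusted p = 3.92e-05). CNGB3, SLC17A8 and SLC6A9 were named after their values were seen. Their calls were lost without whole retina replicate 2 (limma adjusted p = 0.11, 0.379 and 0.112), and SLC17A8 changed sign after quantile normalization. Whichever library was left out, 9 of the 10 ganglion cell, 3 of the 9 cone, 5 of the 7 bipolar and 2 of the 6 amacrine higher calls stayed. Without whole retina replicate 2 the limma adjusted p was 0.0724 for CNGA3 and 0.0505 for GAD2, and without whole retina replicate 1 it was 0.118 for TFAP2A.

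Of 12 ribbon synapse genes, 6 were higher in central than in whole retina and 6 adjusted over the list alone, with a median of 0.54. CABP4, a calcium-binding gene of photoreceptor terminals, averaged 176 ± 26.8 against 77.1 ± 14.7 (limma adjusted p = 0.000115). Of 15 glycolysis entries, 6 were higher and 6 adjusted over the list alone, with a median of 0.36. TPI1, triosephosphate isomerase, averaged 49.7 ± 7.57 against 13.3 ± 1.03 (limma adjusted p = 6.08e-06). Of 18 shared photoreceptor genes, 5 were higher (TULP1, CRX, GUCY2D, CDHR1 and GUCA1B) and 1 lower (IMPG1), and 5 and 0 by limma adjusted over the list alone, with 1 lower at an unadjusted p under 0.05. TULP1, a photoreceptor transport gene, averaged 405 ± 35.4 against 202 ± 21.5 (limma adjusted p = 6.78e-05). Of 13 rod genes, 2 were higher (NRL and CNGB1) and 1 lower (GNGT1), and 0 and 1 by limma adjusted over the list alone, with 2 higher at an unadjusted p under 0.05. GUCA1B and IMPG1 were named after their values were seen. Without whole retina replicate 2, the limma adjusted p was 0.0758 for GUCA1B, 0.178 for IMPG1, 0.226 for NRL, 0.204 for CNGB1 and 0.157 for GNGT1. For the glycolysis genes ENO2 and HK2 it was then 0.0823 and 0.132. Of the 6 glycolysis calls 2, of the 6 ribbon synapse calls 6 and of the 5 higher shared photoreceptor calls 4 stayed whichever library was left out.

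By camera the lists with higher genes in central retina gave adjusted p = 2.74e-06 (ganglion cell), 0.000832 (cone), 0.00237 (bipolar), 0.0193 (amacrine), 0.00174 (ribbon synapse), 0.00604 (glycolysis) and 0.0228 (shared photoreceptor, median 0.24), against adjusted p = 0.208, 0.208, 0.166, 0.25, 0.166, 0.415 and 0.485 with an estimated correlation. The rod list did not pass limma's camera (adjusted p = 0.15, and 0.04 without central retina replicate 2). The shared photoreceptor call was lost without central retina replicate 1 (limma camera adjusted p = 0.0749). Without genes whose names share a start, the bipolar list no longer passed limma's camera (adjusted p = 0.0803).

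Most Müller glia and retinoid genes were lower in central than in whole retina. Of 11 Müller glia genes, 8 were lower and 8 adjusted over the list alone, with a median of −0.72. RLBP1 averaged 199.8 ± 15.9 against 545 ± 23.4 (limma adjusted p = 2.27e-05). Of 3 astrocyte genes, 2 were lower (ALDH1L1 and GJA1, the latter with a shared name start) and 3 adjusted over the list alone, with a median of −1.72. Of 11 retinoid cycle genes, 8 were lower and 8 adjusted over the list alone, with a median of −1.84. LRAT, a retinol-esterifying enzyme gene, averaged 2.82 ± 1.56 against 41.1 ± 9.81 (limma adjusted p = 3.73e-06). Of 13 retinoic acid genes, 8 were lower and 2 higher (RXRG and RARA), and 8 and 2 adjusted over the list alone, with a median of −1.42. ALDH1A1 averaged 1.56 ± 0.309 against 134 ± 35.1 (limma adjusted p = 3.18e-09). At the preset correlation camera gave an adjusted p of 0.00387 for Müller glia, 0.0204 for astrocyte, 0.000331 for retinoid cycle and 0.0224 for retinoic acid genes, and adjusted p = 0.25, 0.212, 0.0768 and 0.166 with an estimated correlation. RARA, named after its values were seen, lost its call without whole retina replicate 2 (limma adjusted p = 0.129). Whichever library was left out, 5 of the 8 Müller glia, 8 of the 8 retinoid cycle and 7 of the 8 lower retinoic acid calls stayed.

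Between central and whole retina, the complement and heat shock lists passed camera narrowly. Of 6 genes of complement and macular degeneration risk, 5 were lower (TIMP3, CFB, APOE, HTRA1, and C3 with a shared name start) and 1 higher (VEGFA), and 5 and 1 adjusted over the list alone, with a median of −1.61. TIMP3 averaged 53.5 ± 5.04 against 678 ± 36.2 (limma adjusted p = 2.21e-08). Of 9 heat shock genes, 4 were lower (CRYAB, HSPE1, HSPD1, and HSPB1 with a shared name start) and 4 adjusted over the list alone, with a median of −0.34. CRYAB averaged 28.4 ± 5.81 against 550 ± 28.6 (limma adjusted p = 4.5e-08). Camera's adjusted p was 0.0499 for each of these 2 lists, and adjusted p = 0.25 and 0.454 with an estimated correlation. Without genes whose names share a start neither passed limma's camera (adjusted p = 0.0722 and 0.119). The complement call was lost without whole retina replicate 1 or central retina replicate 1, 2 or 3 (limma camera adjusted p = 0.0566, 0.0545, 0.0677 and 0.0509). The heat shock call was lost without whole retina replicate 2 or central retina replicate 3 or 4 (limma camera adjusted p = 0.133, 0.0823 and 0.0527). Of 24 oxidative phosphorylation genes, 9 were lower and 1 higher (NDUFB8), and 9 and 1 adjusted over the list alone (limma camera adjusted p = 0.353, and 0.0401 without whole retina replicate 1). Of its 9 lower calls, 3 stayed whichever library was left out, and that on UQCRC2, with a shared name start, was lost without whole retina replicate 2 or central retina replicate 3 (limma adjusted p = 0.223 and 0.0539). SDHC, a succinate dehydrogenase subunit gene, averaged 3.22 ± 0.465 against 21.3 ± 0.361 (limma adjusted p = 3.16e-06). Without whole retina replicate 1 the limma adjusted p was 0.192 for APOE, 0.116 for VEGFA, 0.0596 for HTRA1, 0.0601 for C3 and 0.183 for NDUFB8, and without whole retina replicate 2 it was 0.153 for HSPD1. C3, HTRA1 and NDUFB8 were named after their values were seen.

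Of 6 carotenoid handling genes, 4 were lower in central than in whole retina (GSTP1, APOE, BCO2 and CD36) and 4 adjusted over the list alone. GSTP1, a glutathione transferase gene, averaged 292 ± 86.1 against 634 ± 18.6 (limma adjusted p = 0.00257). Of 3 blood genes, 2 were lower (HBB and an entry under a repeated name) and 2 adjusted over the list alone. Of 6 skeletal muscle genes, 1 was higher (ACTA1) and 1 lower (MB, shared name start), and 1 and 1 adjusted over the list alone. Of 8 immediate early genes, 1 was lower (EGR1) and 1 higher (JUN, shared name start), and 1 and 1 adjusted over the list alone, while the median was −0.13 and camera's direction upward. EGR1 averaged 7.35 ± 0.998 against 20.3 ± 0.594 (limma adjusted p = 0.000208). These 4 lists did not pass camera. The 1 horizontal cell gene did not pass limma. Without whole retina replicate 2 the limma adjusted p was 0.162 for BCO2, 0.0861 for HBB, 0.113 for ACTA1 and 0.305 for JUN, and without whole retina replicate 1 it was 0.192 for APOE.

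The largest differences between central and whole retina by the naming rule were in CAMK2N2, SCRT2 and N4BP3 on the higher side. CAMK2N2, an inhibitor of a calcium-dependent kinase, averaged 63.5 ± 5.36 against 2.71 ± 1.93 (limma adjusted p = 2.03e-07). FAIM, the other gene on that side, has a shared name start and lost its call with the replicate block (limma adjusted p = 0.118). On the lower side, OPTC averaged 0.15 ± 0.0622 against 523 ± 31.8 (limma adjusted p = 3.85e-07). SILV, the older symbol of the melanosome gene PMEL, averaged 0.158 against 241 ± 89.0 (limma adjusted p = 4.5e-08). MYH11, smooth muscle myosin with a shared name start, averaged 1.03 ± 0.111 against 370 ± 100 (limma adjusted p = 1.39e-09). In total 2257 genes were higher and 3549 lower in central retina (limma, adjusted p under 0.05), 671 and 1746 of them at least 2-fold, with a median over all genes of −0.105. The balance depended on the scaling: 2746 and 3087 after median-ratio scaling, 3016 and 2707 at equal library sums, and 3720 and 2541 after quantile normalization. The median over all genes then moved to 0.048 at equal sums and 0.124 after quantile normalization.

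Peripheral retina was compared with the same 2 whole retinas. Genes of stroma, smooth muscle and pigment were again lower in the regional samples. Of 14 stroma genes, 13 were lower and 14 adjusted over the list alone, with a median of −3.65. COL1A2 averaged 0.807 ± 0.441 in peripheral and 97.6 ± 19.4 in whole retina (limma adjusted p = 6.84e-08). All 6 smooth muscle genes were lower and 6 adjusted over the list alone, with a median of −4.91. ACTA2 averaged 5.91 ± 0.626 against 771 ± 68.2 (limma adjusted p = 7.85e-08). All 7 pigment epithelium genes were lower and 7 adjusted over the list alone, with a median of −1.39. TTR averaged 287 ± 58.9 against 1356 ± 93.9 (limma adjusted p = 0.000519). All 7 melanin genes were lower and 7 adjusted over the list alone, with a median of −2.39. MLANA averaged 3.68 ± 0.51 against 144 ± 2.02 (limma adjusted p = 7.55e-09). By camera the adjusted p was 2.72e-10 for stroma, 1.63e-06 for smooth muscle, 0.000315 for pigment epithelium and 2.74e-06 for melanin, and adjusted p = 0.075, 0.129, 0.246 and 0.105 with an estimated correlation. Of the 7 pigment epithelium calls, 6 stayed whichever library was left out.

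Most immune, vascular and lens genes were lower in peripheral than in whole retina. Of 9 immune genes, 8 were lower and 8 adjusted over the list alone, with a median of −3.10. CD74 averaged 29.2 ± 7.23 against 729 ± 595 (limma adjusted p = 1.73e-05). Of 8 vascular genes, 6 were lower and 6 adjusted over the list alone, with a median of −1.57. CDH5 averaged 1.02 against 7.40 (limma adjusted p = 4.5e-06). Of 16 lens genes, 12 were lower and 12 adjusted over the list alone, with a median of −1.51. CRYBB2 averaged 1.25 ± 1.18 against 329 ± 109 (limma adjusted p = 1.1e-07). Of 3 astrocyte genes, 2 were lower (ALDH1L1 and GJA1, the latter with a shared name start) and 2 adjusted over the list alone, with a median of −1.47. The ALDH1L1 call was lost without whole retina replicate 1 (limma adjusted p = 0.0553). The call on the astrocyte list was lost without whole retina replicate 1 or 2 or peripheral retina replicate 2 (limma camera adjusted p = 0.0691, 0.0711 and 0.0579). At the preset correlation camera gave an adjusted p of 0.000232 for immune, 0.00429 for vascular, 2.01e-06 for lens and 0.043 for astrocyte genes, and adjusted p = 0.246, 0.246, 0.129 and 0.246 with an estimated correlation. Of the 8 immune calls, 7 stayed whichever library was left out.

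Most rod, shared photoreceptor, ribbon synapse and amacrine cell genes were higher in peripheral than in whole retina. The ribbon synapse, amacrine and bipolar lists were also higher in central than in whole retina, at medians of 0.54, 0.50 and 0.58. Between the regions these lists did not pass camera, so their rise over whole retina sets neither region apart. Of 13 rod genes, 8 were higher and 10 adjusted over the list alone, with a median of 0.79. NRL, a rod transcription factor gene, averaged 1437 ± 174 against 697 ± 111 (limma adjusted p = 0.0021). Of 18 shared photoreceptor genes, 13 were higher and 14 adjusted over the list alone, with a median of 0.78. TULP1 averaged 496 ± 30.5 against 202 ± 21.5 (limma adjusted p = 2.52e-05). Of 12 ribbon synapse genes, 7 were higher and 8 adjusted over the list alone, with a median of 0.50. CABP4 averaged 199 ± 7.49 against 77.1 ± 14.7 (limma adjusted p = 0.000101). Of 10 amacrine cell genes, 7 were higher and 7 adjusted over the list alone, with a median of 0.50. GAD2, a gene of GABA synthesis, averaged 16.3 ± 2.84 against 7.78 ± 0.148 (limma adjusted p = 0.000865). Of 10 bipolar cell genes, 3 were higher (among them GRIK1 and, with a shared name start, GPR179) and 6 adjusted over the list alone, with a median of 0.39. The GRIK1 call was lost without whole retina replicate 1 (limma adjusted p = 0.107). Whichever library was left out, 2 of the 8 rod, 6 of the 13 shared photoreceptor, 3 of the 7 ribbon synapse and 3 of the 7 amacrine calls stayed. Without whole retina replicate 2 the limma adjusted p was 0.0788 for PDE6A, 0.0526 for SLC24A1, 0.0539 for BSN and 0.0516 for TFAP2C.

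Of 15 cone genes, 1 was higher in peripheral than in whole retina (THRB, shared name start) over all genes and 0 by limma adjusted over the list alone, with 5 higher at an unadjusted p under 0.05 and a median of 0.38. The THRB call was lost without whole retina replicate 1 or peripheral retina replicate 1 (limma adjusted p = 0.185 and 0.0925). The camera adjusted p was 2.93e-05 for rod, 7.97e-08 for shared photoreceptor, 2.93e-05 for ribbon synapse, 0.000755 for amacrine, 0.00276 for bipolar and 0.0139 for cone genes, and adjusted p = 0.246, 0.199, 0.129, 0.199, 0.168 and 0.283 with an estimated correlation. The call on the cone list was lost without whole retina replicate 1 (limma camera adjusted p = 0.0527). By limma 0 of 10 ganglion cell genes passed and 0 adjusted over the list alone, with 1 lower at an unadjusted p under 0.05; the median was −0.07, and camera, with its direction upward, gave adjusted p = 0.978. The 1 horizontal cell gene did not pass limma over all genes and was higher adjusted over the list alone.

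Part of the retinoic acid, oxidative phosphorylation and heat shock genes were lower in peripheral than in whole retina. Of 13 retinoic acid genes, 7 were lower and 1 higher (CRABP1), and 9 and 1 adjusted over the list alone, with a median of −1.12. ALDH1A1 averaged 6.92 ± 1.30 against 134 ± 35.1 (limma adjusted p = 8.91e-08). CRABP1, named after its values were seen, lost its call without whole retina replicate 1 or 2 (limma adjusted p = 0.0798 and 0.055). Of 24 oxidative phosphorylation genes, 8 were lower and 10 adjusted over the list alone, with a median of −0.41. SDHC averaged 2.66 ± 0.69 against 21.3 ± 0.361 (limma adjusted p = 4.5e-06). Of 9 heat shock genes, 3 were lower (CRYAB, HSPE1, and HSPB1 with a shared name start) and 3 adjusted over the list alone, with a median of −0.43. CRYAB averaged 95.3 ± 11.5 against 550 ± 28.6 (limma adjusted p = 4.83e-06). Camera's adjusted p was 0.00765 for retinoic acid, 0.03 for oxidative phosphorylation and 0.0444 for heat shock genes, and adjusted p = 0.129, 0.542 and 0.468 with an estimated correlation. Without genes whose names share a start the heat shock list no longer passed limma's camera (adjusted p = 0.149). That call was also lost without whole retina replicate 2 or peripheral retina replicate 3 (limma camera adjusted p = 0.17 and 0.12). The oxidative phosphorylation call was lost without whole retina replicate 2 (limma camera adjusted p = 0.66). Of the 8 oxidative phosphorylation calls, 3 stayed whichever library was left out, and that on SDHB was lost without whole retina replicate 2 (limma adjusted p = 0.11).

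The other lists did not pass camera between peripheral and whole retina, though without whole retina replicate 1 the corneal list did (limma camera adjusted p = 0.0307). Of 11 retinoid cycle genes, 6 were lower and 0 higher by limma, with 2 higher at an unadjusted p under 0.05, and 6 and 1 adjusted over the list alone. RGR averaged 70.5 ± 13.9 against 185 ± 24.1 (limma adjusted p = 0.00151). Of 11 Müller glia genes, 3 were lower (ABCA8, and CLU and VIM with shared name starts) and 3 adjusted over the list alone, while the list's median was 0.09 and its mean −0.23. Of 15 glycolysis entries, 1 was higher (TPI1) and 1 adjusted over the list alone, while the median was −0.29 and camera's direction upward. TPI1 averaged 25.8 ± 4.32 against 13.3 ± 1.03 (limma adjusted p = 0.00246). Of 6 genes of complement and macular degeneration risk, 3 were lower (TIMP3, CFB, and C3 with a shared name start) and 3 adjusted over the list alone. Of 8 immediate early genes, 4 were lower (EGR1, ATF3, IER2 and NR4A1) and 4 adjusted over the list alone. Of 7 corneal genes, 3 were lower (S100A9, S100A8 and ALDH3A1) and 5 adjusted over the list alone. The S100A9 call was lost with the replicate block and after quantile normalization (limma adjusted p = 0.0714 and 0.0764). Of 6 carotenoid handling genes, 2 were lower (GSTP1 and CD36) and 2 adjusted over the list alone. Of 3 blood genes, 2 were lower (HBB and an entry under a repeated name) and 2 adjusted over the list alone, and of 6 skeletal muscle genes 1 was lower (MB, shared name start) and 1 adjusted over the list alone. Without whole retina replicate 1 the limma adjusted p was 0.196 for C3, 0.176 for ATF3, 0.371 for IER2, 0.104 for NR4A1 and 0.227 for S100A8, and without whole retina replicate 2 it was 0.206 for ALDH3A1 and 0.15 for HBB.

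The largest differences between peripheral and whole retina by the naming rule were CAMK2N2 and SCRT2 on the higher side and ACTA2 and CRYBB2 on the lower side. CAMK2N2 averaged 22.0 ± 3.36 against 2.71 ± 1.93 (limma adjusted p = 1.35e-05). SCRT2, a transcriptional repressor gene, averaged 11.1 ± 2.04 against 2.07 ± 0.099 (limma adjusted p = 3.84e-05). RPE, SLC25A31, MYH11 and CXCL13 also met the rule and have shared name starts. CXCL13 was listed at 0 in all 7 regional libraries. The calls on SLC25A31 and RPE were lost without whole retina replicate 1 (limma adjusted p = 0.109 and 0.0546). In total 1173 genes were higher and 2904 lower in peripheral retina (limma, adjusted p under 0.05), 152 and 1558 of them at least 2-fold, with a median over all genes of −0.075. The higher count was 697 without whole retina replicate 2. The balance depended on the scaling: 1742 and 2482 after median-ratio scaling, 2223 and 2226 at equal library sums, and 3174 and 2063 after quantile normalization. The median over all genes then moved to 0.108 at equal sums and 0.165 after quantile normalization.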

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

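The libraries of central retina were screened with Dixon's test for single values far from the other 3, and the items screened were chosen after results were seen. The screen took 154 items, 3 library measures and otherwise named genes, and 12 were past its limit, where chance alone would give about 1 in 20. Another 31 list members that did not pass limma were left out of it, and 4 of those would have been past the limit.

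In central retina replicate 4, NEFM was 390.8, against 218.58 to 237.37 in the other central libraries. WIF1 was 142.46 there, against 181.81 to 188.86. ALDOC was 1851.04, against 1200.44 to 1300.24. RP1, whose name shares its start with other genes, was 54.85, against 123.52 to 130.51. CRYBA4 was 0.55, against 0.13 to 0.19, and KRT4 was 0.04, against 0 in the other 3. The cause was not tested.

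In central retina replicate 2, COL9A1 was 4.42, against 0.36 to 0.97, and GRIK1 was 44.9, against 30.99 to 33.02. KCNJ13, with a shared name start, was 2.71, against 0.77 to 1.05. In central retina replicate 3, ALDH1L1 was 1.56, against 0.99 to 1.07. In central retina replicate 1, CACNA1F was 94.03, against 77.6 to 80.14. MB, with a shared name start, was 0.05 there, against 0 in the other 3. The cause was not tested for these either.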

How the results depend on the processing

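The pseudocount, the 3 scalings, the fit without genes sharing a name start, the list counts without the shallowest library and the list tests and list counts without each library were chosen after seeing the data; the other alternatives were planned. Of 308 results for named genes, 223 kept their direction and side of the threshold in every setting (64 of 80 in central against peripheral retina, 16 of 34 in whole retina against whole eye, 79 of 109 in central and 64 of 85 in peripheral against whole retina). The table of alternatives leaves out 154 results of list members that did not pass; 24 of those changed sign in some setting and 42 passed in some setting.

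With an estimated correlation, camera called 1 list instead of 11 between the regions, 2 instead of 9 in whole retina against whole eye, and 0 instead of 20 and 17 in central and peripheral against whole retina. Without genes sharing a name start, limma's camera gained complement between the regions (adjusted p = 0.0325) and ganglion cell and immediate early genes in whole retina against whole eye (0.0275 and 0.0346). In fits of only the compared groups limma's camera gained immune, oxidative phosphorylation, complement and immediate early genes between the regions (adjusted p = 0.0394, 0.0463, 0.042 and 0.0337), and rod, ganglion cell, retinoid cycle and immediate early genes in whole retina against whole eye (0.00796, 0.0116, 0.0465 and 0.0271). Leaving out each library left camera 11 to 14, 6 to 10, 18 to 21 and 14 to 17 lists. A minimum mean of 10 left 604 lower genes (1045 as reported) between the regions, 7 and 97 (20 and 251) in whole retina against whole eye, 2016 lower (3549) in central and 740 and 1628 (1173 and 2904) in peripheral against whole retina. In whole retina against whole eye, the higher count was 31 without the filter, 7 at a pseudocount of 0.1 and 35 after quantile normalization. After quantile normalization 3720 genes were higher in central and 3174 in peripheral against whole retina, and equal sums gave 2223 in the latter.

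Fits of only the compared groups gave 1690 and 1215 between the regions, 11 and 152 in whole retina against whole eye, 2043 and 3187 in central and 913 and 2498 in peripheral against whole retina. Adding the replicate block to those fits gave 1072 and 709, 6 and 114, 1522 and 2238, and 547 and 1870. Residuals of equally numbered central and peripheral libraries correlated at −0.14, −0.06 and 0.36, so the numbers may not mark pairs throughout. Central retina replicate 1 correlated best with peripheral retina replicate 2 (0.36), and central retina replicate 2 with peripheral retina replicate 1 (0.35). Samples paired under unequal numbers stay possible, and no fit used such pairs. Equally numbered whole eyes and whole retinas correlated at 0.19 and 0.19, against −0.19 for unequal numbers, and 2 pairs are too few to decide. Equally numbered regional and whole retina libraries gave −0.09 to 0.2. Leaving out each library in turn gave 829 to 1503 higher and 499 to 1386 lower genes between the regions, and 14 to 493 and 215 to 292 in whole retina against whole eye. It gave 1521 to 2249 and 3023 to 3736 in central, and 697 to 974 and 2295 to 2710 in peripheral against whole retina. A group left with 1 library is assumed to vary like the others. SLC17A8 changed from −0.36 to 0.071 in central against whole retina after quantile normalization. Without central retina replicate 1, 10 ganglion cell, 7 Müller glia, 8 retinoid cycle and 7 glycolysis genes passed between the regions. The planned count tests (DESeq2, limma-voom), count-based size factors and thinning to equal depth need counts and were not run.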

Other observations

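The families in the next paragraph, formed by the letters that start gene names, were chosen after seeing the data; so were the splits of the libraries, the test of name starts, the scaling tests and, in the test of carried-over tissue, the use of all members and the interval, while the test of related genes and the limits of 80% and 50% for carried-over tissue were written before their values were seen.

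Of 49 families of genes without shared name starts, 3 passed camera in central against whole retina, 5 in peripheral against whole retina and 0 in the other comparisons, and 0 anywhere with an estimated correlation. Ribosomal protein genes (RPL) were lower in central than in whole retina in 11 of 13 cases, with a median of −1.06 and −0.94 to −0.8 under other scalings (limma camera adjusted p = 0.0017, and adjusted p = 0.809 with an estimated correlation). RPL9 averaged 75.4 ± 9.38 against 317 ± 32.3 (limma adjusted p = 7.27e-07). In peripheral retina 11 of 13 were lower, with a median of −0.9 (limma camera adjusted p = 0.000617, and adjusted p = 0.718 with an estimated correlation). Collagen genes (COL) were lower in 16 of 21 cases in central retina (limma camera adjusted p = 0.000276, and adjusted p = 0.421 with an estimated correlation) and in 14 in peripheral retina (limma camera adjusted p = 0.000208, and adjusted p = 0.458 with an estimated correlation). Aldehyde dehydrogenase genes (ALDH) were lower in 12 of 13 cases in central and 9 in peripheral retina (limma camera adjusted p = 0.000922 and 0.00156, and adjusted p = 0.421 and 0.458 with an estimated correlation). Zinc finger genes (ZNF) were higher in 23 of 152 cases and lower in 1 in peripheral retina, and centrosomal genes (CEP) were higher in 6 of 13 (limma camera adjusted p = 7.65e-05 and 0.0196, and adjusted p = 0.641 and 0.718 with an estimated correlation). What moved these families was not tested.

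Some values appear to sit under the name of another gene whose name starts alike. Among 2131 pairs of such names, 55 showed exchanged values between libraries, against 4 to 23 in 100 draws of control pairs (permutation p = 0.0099, the smallest possible), which is consistent with names matched by their start when the tables were made. Related genes sharing reads would act on gene families too, but 0.25% of 5273 family pairs without a shared start showed the pattern, against 2.58% of pairs with one. In FAIM and FAIM3, the central libraries gave 47.44 to 67.11 and 0.03 to 0.08, and the peripheral ones 0.03 to 0.1 and 26.44 to 33.18. How the tables were made was not observed, and genes exchanged in all libraries of a group cannot be told from a difference between groups.

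Genes of pigment epithelium, melanin synthesis, stroma and smooth muscle were higher in whole retina than in both regions. Their 22 abundant members without shared name starts stood at a median of 1.07 times their level in the whole eye. Over 4 scalings the median log2 difference nearest to 0 was −2.29. The median over all genes lay only between −0.1 and 0.17 under these scalings, and shifts of that size do not account for it. All 22 were over 2-fold above both regions, where a mixture of both would lie between them. For these genes this argues against whole retina samples made up only of such regional tissue. Other eye layers kept with the whole retina samples, and parts of the retina in neither regional sample, stay open. No test was run that would have come out otherwise without them.

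Pigment epithelium and melanin genes were lower in central than in peripheral retina. If 1 pigmented tissue had been carried over into the peripheral samples, its genes would show similar shares of their level in whole retina, but 38.5% of all members (5 of 13, 95% exact interval 13.9% to 68.4%, taking genes as independent) lay within 2-fold of their median share of 13.2%, against 8 of the 9 without shared name starts around 16.4%. Low shares were found for RPE65 (0.51%), DCT (2.95%) and TYR (4.68%), with shared name starts, and for MLANA (2.5%) and SILV (2.14%, outside the lists). Over 4 scalings the median log2 difference nearest to 0 was −1.42. The median over all genes, at −0.04 to −0.01, is too small to account for it. All members fall below the limit of 50% and the 9 above that of 80%, and the interval for all members includes 50%, so carried-over tissue stays open, as does a difference between the regions themselves.

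Of the 35 ways to split the 7 central and peripheral libraries into 4 and 3, 1, the real one, called as many as 2538 genes, and the highest other called 66, so the calls are not what an arbitrary grouping of these libraries gives.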
